A study of Homo sapiens with 6 samples.

How the data were processed

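RNA from HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen, was sequenced 24 h after transfection with FuGENE, a transfection reagent. Per the labels, 3 libraries came from cells given an empty vector and 3 from cells given a pCMV6 plasmid that encodes SEHBP fused to EGFP, a green fluorescent protein. The labels call the samples of each group biological replicates and do not say whether they were separate cultures or transfection days, so p-values measure only the spread between these samples, which may be technical. Total RNA was purified from pelleted cells and sequenced by a service provider, per the labels' protocols. Whether the libraries kept strand is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

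The authors deposited 1 table of TPM, in which all transcripts of a library sum to a fixed total, for each gene symbol and library. The values were made with kallisto and genome build GRCh37.p13, per the submitters' processing notes. The version of kallisto and the step from transcripts to genes are not given in the sources used here. Kallisto divides reads among similar transcripts by estimated abundance, so values of near-identical copies, pseudogenes and overlapping genes are uncertain. The table holds 21695 symbols, of which 5137 were listed at 0 in all 6 libraries. The listed TPM summed to between 567234 and 659115 per library, below that total, so part of each library lies in transcripts not used here. TPM keep no sequencing depth, so the depth per library is unknown, no counting interval or detection floor can be given, and the spread between replicates is the only measure of error.

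Columns were matched to samples by group name and replicate number. The treated columns carry the construct name SEP10-gfp in place of SEHBP-EGFP. They were taken as the SEHBP-EGFP libraries because no other sample has a fluorescent tag.

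TPM are not counts, so genes were tested on a log scale with limma 3.58.1 in R 4.3.3. For the 9332 genes with a mean of at least 1 TPM over the 6 libraries, log2(TPM + 1) was fitted with the group as the only term. The moderated two-sided test with a mean-variance trend (limma-trend) was adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Fold changes are SEHBP-EGFP over empty vector on the log2(TPM + 1) scale, which understates the change of genes with low TPM. Values are means ± SD over 3 libraries, and errors of log2 fold changes are standard errors. "Rose" and "fell" are used of genes past the threshold.

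The design, the 32 gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. The lists cover pathways, complexes and markers of other cell types, and 1 of them holds all symbols with the prefix ZNF. The 27 lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the 27 lists. Camera was repeated with a correlation estimated from the data, and fry tested whether the members of a list moved, on balance, one way. List medians are given relative to the median of all tested genes. Genes were named by rule: the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 TPM and no overlap between the groups, the 5 largest gains and 5 largest losses in mean TPM among called genes, and up to 4 members of each list described. List members were the called ones with the largest changes, or those with the smallest p where fewer than 2 were called. The rule chose 80 genes, and 22 more were chosen after their values were seen; some of these are not reported here.

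The fit was tested on simulated data for this comparison with 9332 genes, 200 of them changed. It recovered 74% of genes changed 1.5-fold, 100% at 2-fold, 98% at 3-fold and 100% at 4-fold, and called 22 unchanged genes. A list shifted on purpose was called, and 0 unshifted lists were. The simulated genes varied independently, so this does not show how often lists of correlated genes are called falsely.

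Alternative settings fixed at that point were a pseudocount of 0.1 or 5 TPM, no filter on low TPM or a mean of at least 5 TPM, scaling by the median of ratios or by a trimmed mean (trims of 0.3 for ratios and 0.05 for means), the replicate number as a block, no mean-variance trend, an estimated correlation in camera, and leaving out each library in turn. Chosen after seeing the data were a fit with GH1 left out and the other genes rescaled to a common total, and a loess correction of each library for GC content (span 0.3). GC content, transcript types and gene types came from GENCODE 29, where 21462 symbols matched directly and 158 through an older symbol. GENCODE 29 uses another genome build than the deposited values, so no coordinates are given. In the table of current gene names, 20917 symbols matched. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.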

Results

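The study compared the transcriptomes of HEK293T cells given an empty vector and of cells given a plasmid for SEHBP-EGFP. SEHBP is a protein encoded by a short open reading frame that the study's title calls a regulator of transcription. Each group had 3 libraries, with expression given as TPM per gene symbol. The listed genes summed to 567234, 649747 and 647652 TPM in empty vector libraries 1 to 3, and to 659115, 653977 and 659047 TPM in the SEHBP-EGFP libraries, so empty vector library 1 had the lowest total. Pearson's r of log2(TPM + 1) across genes, which are not independent replicates, was 0.9872 to 0.9911 between empty vector libraries, 0.9892 to 0.9907 between SEHBP-EGFP libraries and 0.9807 to 0.9875 between groups. The first principal component held 43.4% of the variance and separated the groups, and the second held 19.2% and set empty vector library 1 apart. With 0 rows named SEHBP, EGFP or GFP, the transgene was not analysed here. Cells given EGFP alone were not analysed here either, so each difference is between the whole SEHBP-EGFP plasmid and the empty vector.

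In cells with SEHBP-EGFP, 5 of 17 heat shock genes rose, while 9 of 17 p53 targets and 10 of 17 replication-dependent histone genes fell. TPM assigned to GH1 also rose, but may include reads of the plasmids, so a rise of the cells' own GH1 was not shown. No list was called with an estimated correlation between genes. Of 9332 genes tested with limma-trend, 940 passed the adjusted threshold, of which 87 rose and 853 fell. Without a filter on low TPM 272 of 16558 passed, of which 27 rose and 245 fell. Changes were mostly small, with a median absolute log2 fold change of 0.55 among called genes, and 6 genes rose and 53 fell by at least 2-fold. These numbers were 7 and 31 with median-of-ratios scaling, 7 and 30 with trimmed-mean scaling, 9 and 20 with a correction for GC content, 11 and 117 with a pseudocount of 0.1, 2 and 6 with a pseudocount of 5, 2 and 27 without a filter, and 3 and 26 with a mean of at least 5 TPM. The groups did not overlap in 939 of the called genes, but this rests on the same values as the calls and adds no support. They did not overlap in 31.3% of tested genes against 10% by chance. The 10% assumes no shift common to many genes, such as a scale difference between the groups. The split between rises and falls depended on scaling. Median-of-ratios scaling gave 334 rises and 536 falls, trimmed-mean scaling 397 and 520, and the correction for GC content 293 and 350. The median log2 fold change of all tested genes was -0.087 as deposited, and 0.0032, 0.013 and 0.022 in these 3 settings. The 940 genes kept their sign in all 3, and 623, 607 and 434 of them also passed the threshold there. The number of called genes was 480 without empty vector library 2, 433 without empty vector library 3, 402 without SEHBP-EGFP library 1 and 379 without SEHBP-EGFP library 3. Beside single genes below, kept or lost calls and the highest adjusted p are over the fits with 1 library left out, unless another setting is named. Such fits have fewer libraries and so less power. A lost call therefore need not mean that the change rested on 1 library. Of 86 called genes followed through the settings in which they were tested, 59 lost their call without a filter on low TPM and 25 with the correction for GC content.

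**Figure D1:**
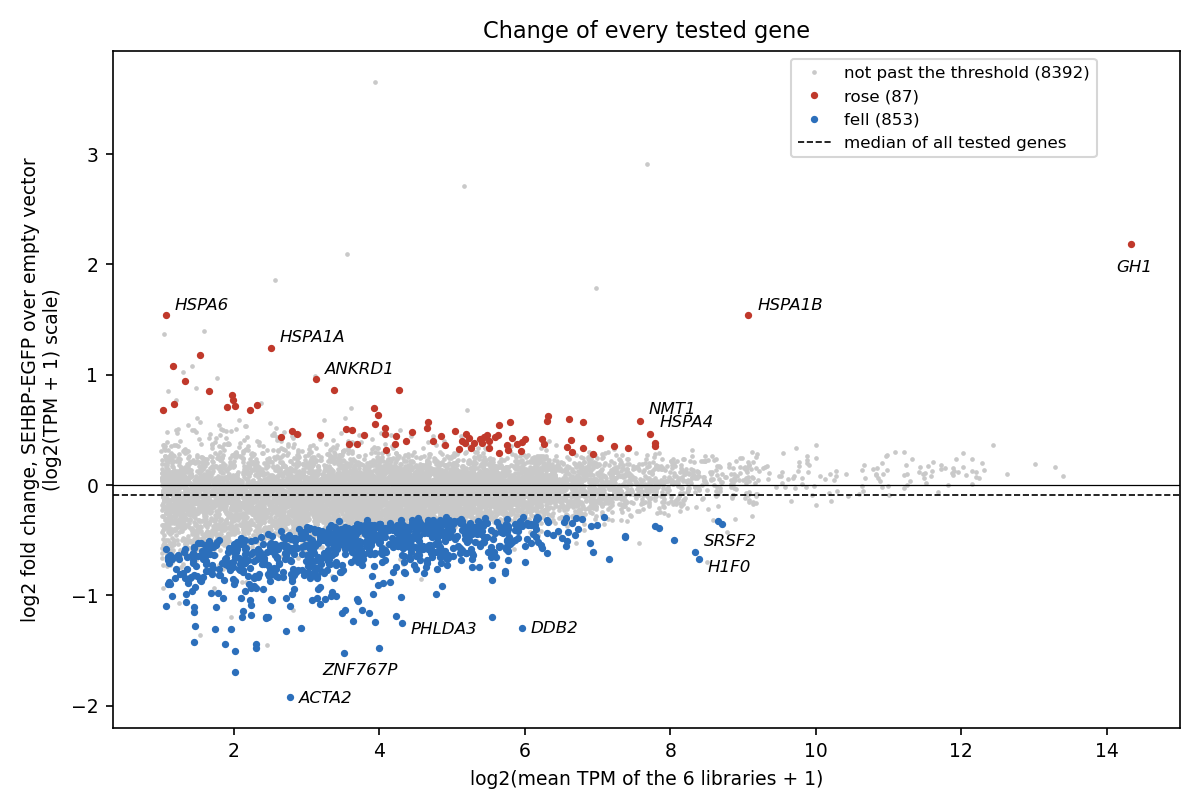
Log2 fold change of each of 9332 tested genes, SEHBP-EGFP over empty vector, against its mean level over the 6 libraries. Red points are the 87 genes that rose, blue points the 853 that fell and grey points those not past the threshold, and the dashed line marks the median of all tested genes at -0.087.

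GH1, the gene of pituitary growth hormone, had the largest log2 fold change among rises and was already abundant with the empty vector. This ranking depended on the pseudocount of 1 TPM: with 0.1, HSPA6, which was below 0.1 TPM with the empty vector, rose by 3.72 and GH1 by 2.18 on the log2 scale. It was at 10068, 6297 and 6471 TPM in the empty vector libraries (7612 ± 2129) and at 32924, 30573 and 38115 TPM with SEHBP-EGFP (33871 ± 3859), a log2 fold change of 2.18 ± 0.21 (adjusted p = 0.000904). GH1 held 4.67 to 5.78% of the listed TPM with SEHBP-EGFP and 0.969 to 1.77% with the empty vector. It ranked 1 among listed genes in every SEHBP-EGFP library and in empty vector library 1, and 5 in the other two. Its near-identical neighbours GH2 and CSH1, chosen after their values were seen, also rose, by 0.94 and 1.08 on the log2 scale, but did not exceed 2.43 and 2.39 TPM in any library. Reads can be divided wrongly among these genes. Reads of a growth hormone region carried by the plasmids may also have been assigned to GH1. The change of GH1 therefore need not be one of the cells' own gene. The calls of GH2 and CSH1 were lost without empty vector library 2 or 3 or SEHBP-EGFP library 1 or 3 (adjusted p up to 0.0654 and 0.113).

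Other large rises were of single genes. ANKRD1, a target of YAP signalling, went from 4.91 ± 0.0818 to 10.6 ± 1.5 TPM (log2 fold change 0.96 ± 0.12, adjusted p = 0.0031). The ubiquitin ligase gene ITCH went from 6.36 ± 0.644 to 12.4 ± 0.954 TPM (0.86 ± 0.11), and the pseudogene CCDC144B, which resembles other gene copies, from 12.6 ± 1.7 to 23.8 ± 3.84 TPM (0.86 ± 0.14). NMT1, an N-myristoyltransferase gene, went from 153 ± 11.1 to 230 ± 26.1 TPM (adjusted p = 0.00848). PALM3, TCP10L, RPL35P5, HBA1 and CCDC124 rose by 0.85, 0.81, 0.77, 0.72 and 0.38 on the log2 scale. The highest adjusted p with 1 library left out was 0.0732 for PALM3, 0.117 for TCP10L, 0.0976 for RPL35P5, 0.110 for HBA1 and 0.181 for CCDC124, whose call was lost whichever library was left out. PALM3 lost its call without empty vector library 3 or SEHBP-EGFP library 1 or 3, TCP10L without these or empty vector library 2, HBA1 without empty vector library 1 or 3 or SEHBP-EGFP library 1 or 3, and RPL35P5 kept its call only without SEHBP-EGFP library 2. RPL35P5 and HBA1 have near-identical copies.

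ACTA2, the gene of smooth muscle actin, had the largest fall with the pseudocount of 1 TPM, though not with 0.1 or 5, from 9.85 ± 3.82 to 1.85 ± 0.985 TPM (log2 fold change -1.92 ± 0.31, adjusted p = 0.00678). The ranking also depended on single libraries: with 1 library left out SMG1P4 reached -2.38, while ACTA2 went no lower than -2.26. APBB3, whose protein binds the amyloid precursor protein, went from 8.38 ± 0.123 to 2.76 ± 0.485 TPM (-1.33 ± 0.12, adjusted p = 0.000843), and the pseudogene ZNF767P from 16 ± 3.81 to 4.86 ± 0.242 TPM (-1.52 ± 0.15). CCDC157 went from 6.26 ± 1.38 to 1.64 ± 0.134 TPM, and GUCY1B2, related to guanylate cyclase subunits, from 4.43 ± 2.06 to 0.907 ± 0.0814 TPM. The histone H4 gene HIST2H4B and the readthrough transcript MSH5-SAPCD1 had log2 fold changes of -1.47 and -1.51, and both share sequence with other genes, so their values are uncertain. SMG1P4, CCHCR1 and PMS2P10 fell by 1.69, 1.48 and 1.31 on the log2 scale. SMG1P4 kept its call only without SEHBP-EGFP library 2, CCHCR1 only without empty vector library 3 or SEHBP-EGFP library 3, and PMS2P10 only where an empty vector library was left out (adjusted p up to 0.150, 0.0741 and 0.0847). SMG1P4 and PMS2P10 have near-identical copies.

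By TPM, the largest losses included genes of chromatin and RNA-binding proteins. The linker histone gene H1F0 went from 415 ± 91.0 to 257 ± 16.5 TPM (log2 fold change -0.67 ± 0.14, adjusted p = 0.0184) and the splicing factor gene SRSF2 from 389 ± 16.7 to 256 ± 16.2 TPM (-0.60 ± 0.09, adjusted p = 0.00493). RBMX, an RNA-binding protein gene, went from 472 ± 41.4 to 368 ± 28.0 TPM, and ENSA, whose protein inhibits a phosphatase in mitosis, from 447 ± 21.5 to 357 ± 20.3 TPM. H1F0 lost its call without SEHBP-EGFP library 1 or 3, with either scaling, with the correction for GC content and without a filter on low TPM (adjusted p up to 0.0928). With 1 library left out, RBMX and ENSA kept theirs only without empty vector library 1 (adjusted p up to 0.180 and 0.166), and both lost them with trimmed-mean scaling, with the correction for GC content and without a filter.

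**Figure D2:**
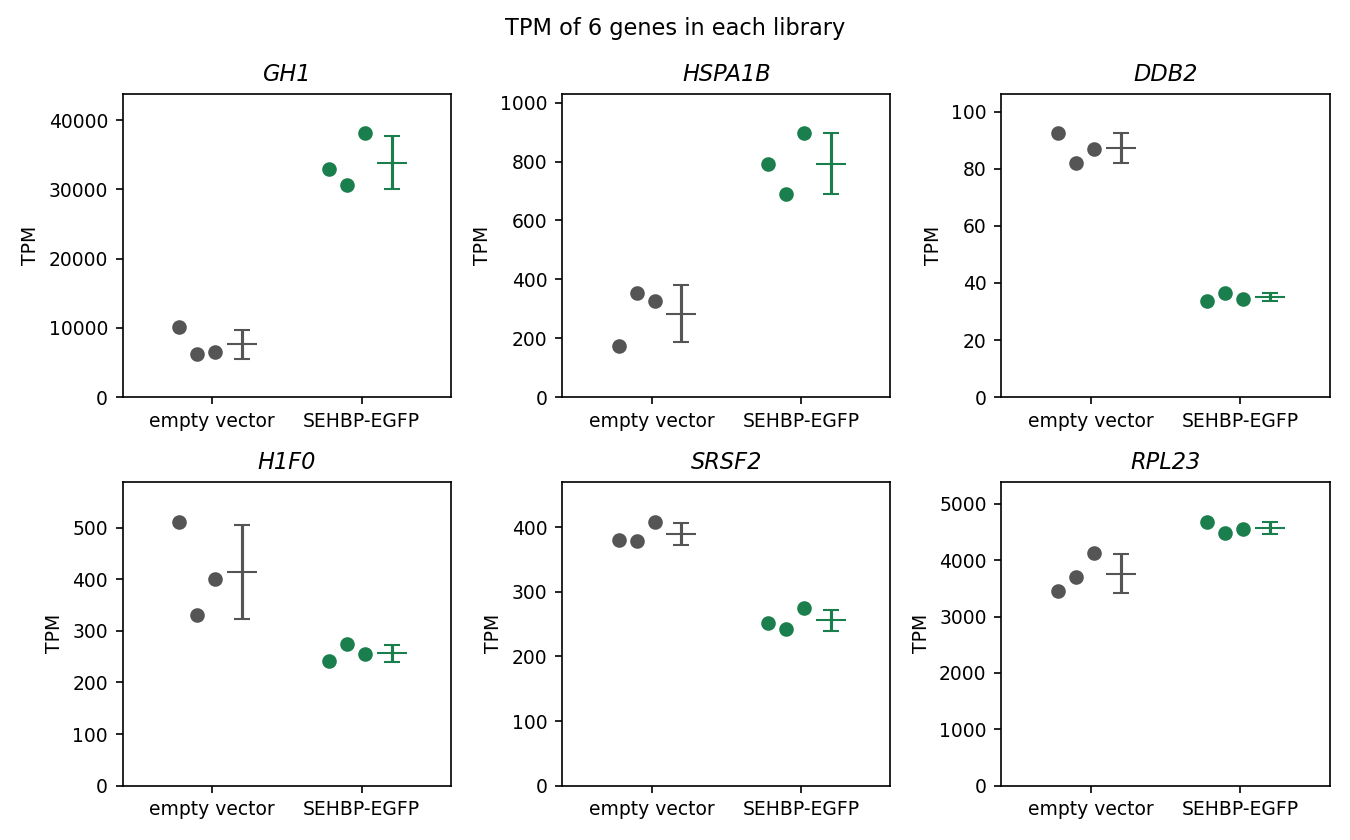
TPM of 6 genes in each library of the empty vector and SEHBP-EGFP groups, as points with the mean ± SD of 3 libraries beside them. GH1 lay at 6297 to 10068 TPM with the empty vector and 30573 to 38115 TPM with SEHBP-EGFP, and RPL23, with means of 3760 and 4573 TPM, did not pass the threshold.

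Of 17 genes of the heat shock response 5 rose, among them inducible chaperones. HSPA1B, an inducible HSP70 gene, went from 284 ± 97.2 to 793 ± 103 TPM (log2 fold change 1.54 ± 0.23, adjusted p = 0.00557). HSPA6, a stress-induced relative, went from 0.0673 ± 0.0179 to 2.11 ± 0.173 TPM (adjusted p = 0.00102), and the cochaperone gene DNAJB1 from 64.1 ± 10.0 to 85 ± 4.50 TPM (0.41 ± 0.11, adjusted p = 0.0474). With a mean of 1.09 TPM over the 6 libraries, HSPA6 was close to the filter. It was tested in only 3 fits with 1 library left out, and kept its call in these. HSPA1A, a near-identical copy of HSPA1B whose reads cannot be divided with certainty, went from 2.39 ± 1.1 to 6.97 ± 2.24 TPM. In the list 0 genes fell and 12 did not pass, and 6 rose when adjusted over the list alone. The number that rose was 6 with either scaling and 8 with the correction for GC content. The fifth was CHORDC1, named after its value was seen (0.35, adjusted p = 0.0277). The list lay 0.26 above all tested genes (camera adjusted p = 7.1e-07, but adjusted p = 0.669 with an estimated correlation). HSPA4, of the HSP110 family, had 1 of the largest gains in TPM, from 177 ± 4.07 to 245 ± 21.6 (adjusted p = 0.0109). Empty vector library 1 had the lowest TPM of all 6 libraries in HSPA1B, HSPA1A, DNAJB1 and HSPA4, but not in HSPA6. For HSPA1B it was at 173 TPM, against 352 and 326 in the other empty vector libraries. With 1 library left out the list was called each time, at 0.21 to 0.32 above all tested genes. HSPA1A lost its call without SEHBP-EGFP library 1 or 3 and HSPA4 without library 3 (adjusted p up to 0.0838 and 0.0610), DNAJB1 kept its call only without empty vector library 1 or 2, and CHORDC1 only without empty vector library 1 (up to 0.156 and 0.116).

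Of 17 tested genes of the p53 target list 9 fell. DDB2, a gene of nucleotide excision repair, went from 87.1 ± 5.24 to 35.0 ± 1.44 TPM (log2 fold change -1.29 ± 0.08, adjusted p = 0.000183). PHLDA3, a repressor of AKT, went from 27 ± 5.32 to 10.7 ± 0.569 TPM (-1.25 ± 0.13), the oxidoreductase gene TP53I3 from 14.4 ± 1.41 to 5.89 ± 0.317 TPM (-1.16 ± 0.11) and the sestrin gene SESN1 from 21.8 ± 1.18 to 11.4 ± 0.641 TPM (-0.88 ± 0.09). In the list 0 genes rose and 8 did not pass, and 13 fell when adjusted over the list alone. The number that fell was 9 with either scaling and with the correction for GC content. All 17 had log2 fold changes below 0, as they did with both scalings, and 16 did with the correction for GC content. The list lay at -0.58 relative to all tested genes (camera adjusted p = 2.6e-08, but adjusted p = 0.233 with an estimated correlation). With the preset correlation it was called in all 16 alternatives, at -0.62 to -0.32, the smallest with a pseudocount of 5.

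Of 17 tested replication-dependent histone genes, most of whose mRNAs lack a poly(A) tail, 10 fell. HIST1H2AC went from 6.56 ± 0.501 to 2.27 ± 0.226 TPM (log2 fold change -1.21 ± 0.12, adjusted p = 0.00102), HIST1H2BJ from 16.4 ± 4.47 to 7.39 ± 1.7 TPM (-1.04 ± 0.19) and HIST1H2BD from 8.39 ± 2.04 to 3.83 ± 0.445 TPM (-0.94 ± 0.15). HIST1H4H went from 2.44 ± 0.922 to 0.642 ± 0.356 TPM, a call lost without SEHBP-EGFP library 1 or 2 (adjusted p up to 0.0625). Empty vector library 1 had the highest TPM of all 6 libraries in each of these genes. For HIST1H2BJ it was at 21.2 TPM, against 12.4 and 15.5 in the other empty vector libraries. With 1 library left out the list was called each time, at -0.65 to -0.51 relative to all tested genes. In the list 0 genes rose and 7 did not pass, and 10 fell when adjusted over the list alone. The number that fell was 7 with either scaling and with the correction for GC content. The list lay at -0.60 relative to all tested genes (camera adjusted p = 0.000112, but adjusted p = 0.446 with an estimated correlation). With the preset correlation it was called in all 16 alternatives (adjusted p up to 0.0120), at -0.75 with a pseudocount of 0.1, -0.40 with a mean of at least 5 TPM, and -0.20 with a pseudocount of 5 or without a filter on low TPM. Many histone genes are near-identical, so the values of single members are uncertain.

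**Figure D3:**
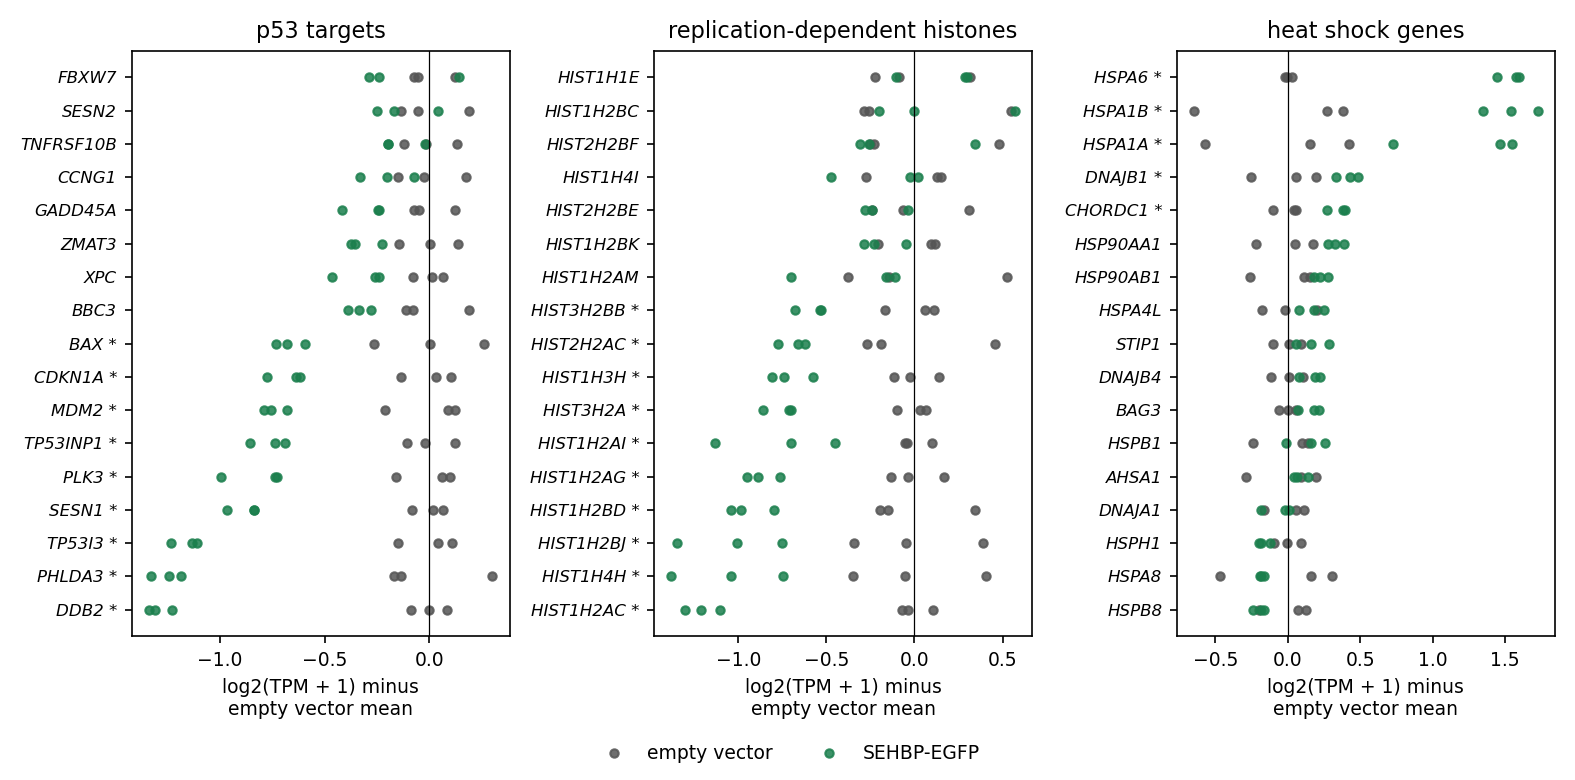
Log2(TPM + 1) of each tested member of the p53, histone and heat shock lists in each library, minus the mean of the empty vector libraries, with an asterisk at genes past the threshold. Of 17 members each, 9 fell in the p53 list, 10 fell in the histone list and 5 rose in the heat shock list.

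Of genes of chromatin regulators 5 fell, without a call for their lists, and all 5 lost their calls with the correction for GC content. Of all 9332 tested genes 853 fell, so the falls among the 24 and 31 genes of these lists were near the share of all genes. Among 24 histone chaperones and variant histones 2 fell, also when adjusted over the list alone: H1F0 and SUPT6H, a chaperone of transcription elongation (57.6 ± 1.30 to 42.7 ± 2.30 TPM, adjusted p = 0.0107). Camera did not call the list (adjusted p = 0.735). In it 1 gene rose and 1 fell with median-of-ratios scaling, 3 rose and 1 fell with trimmed-mean scaling, and 1 rose and 0 fell with the correction for GC content, where H1F0 and SUPT6H both lost their calls (adjusted p up to 0.0791). Of 31 genes of Polycomb and DNA methylation 3 fell and 28 did not pass, and 5 fell when adjusted over the list alone (camera adjusted p = 0.606). These were the acetyltransferase gene KAT2A (37.4 ± 11.5 to 21.4 ± 1.7 TPM), RING1 (39.1 ± 2.56 to 29.3 ± 0.924 TPM) and CBX8 (12 ± 0.678 to 9.03 ± 0.972 TPM). With either scaling 1 of the 31 fell and 2 rose, and with the correction for GC content 0 changed. SUPT6H and RING1 lost their calls without SEHBP-EGFP library 3, RING1 also without empty vector library 2 or 3, CBX8 without any of these or SEHBP-EGFP library 2, and KAT2A kept its call only without empty vector library 1 (adjusted p up to 0.0599, 0.0760, 0.162 and 0.132).

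Splicing factor genes fell in part. RBM5, a regulator of alternative splicing, went from 58.7 ± 5.67 to 32.6 ± 9.32 TPM (log2 fold change -0.86 ± 0.17, adjusted p = 0.014). SRSF6, a serine- and arginine-rich factor like SRSF2, went from 57.0 ± 2.92 to 34.2 ± 0.687 TPM (-0.72 ± 0.08, adjusted p = 0.00166) and LUC7L from 30.0 ± 1.5 to 18.2 ± 3.20 TPM (-0.71 ± 0.12). In the list of splicing and nuclear non-coding RNA genes 6 of 16 fell, 0 rose and 10 did not pass, and 9 fell when adjusted over the list alone. With either scaling, and with the correction for GC content, 5 fell and 1 rose. The list lay at -0.19 relative to all tested genes (camera adjusted p = 0.0350, but adjusted p = 0.669 with an estimated correlation). Camera's call was lost without empty vector library 1 or 3 or SEHBP-EGFP library 2 and with a pseudocount of 0.1 (adjusted p up to 0.0632).

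Zinc finger genes with the prefix ZNF, most of which encode DNA-binding proteins, had a lower median as a family than all tested genes. ZNF783 went from 7.96 ± 0.615 to 3.91 ± 0.295 TPM (log2 fold change -0.87 ± 0.11, adjusted p = 0.00341), ZNF583 from 2.36 ± 0.532 to 0.810 ± 0.219 TPM (-0.89 ± 0.17) and ZNF789 from 6.42 ± 0.879 to 3.29 ± 0.933 TPM (-0.81 ± 0.17). Of 282 tested, 29 fell, 252 did not pass and 1 rose, ZNF81, named after its value was seen (0.68, adjusted p = 0.0288). Adjusted over the list alone, 39 fell and 1 rose. The number that fell was 14 with median-of-ratios scaling, 13 with trimmed-mean scaling and 7 with the correction for GC content, and 3, 3 and 1 rose. Of all 9332 tested genes 853 fell, and 536 and 520 with these scalings, and 350 of 9325 with the correction. Called falls were thus about as frequent among all tested genes as in this family. The family lay at -0.12 relative to all tested genes (camera adjusted p = 0.000291, but adjusted p = 0.669 with an estimated correlation). Without empty vector library 1, which had the lowest listed total, it lay at -0.078 and was not called (adjusted p = 0.0710), and with a pseudocount of 5 it lay at -0.058. Camera does not match on expression: the fifth of genes with the lowest mean expression had a median log2 fold change of -0.16, against -0.21 for this family. ZNF583 lost its call without empty vector library 3 and ZNF789 without empty vector library 2 (adjusted p = 0.0502 and 0.0592), and ZNF81 kept its call only without empty vector library 1 or 3 (up to 0.0927).

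Immediate early genes, induced within minutes by growth factors and stress, were higher as a list. DUSP1, a MAP kinase phosphatase gene, rose from 17.4 ± 2.0 to 24.5 ± 0.328 TPM (log2 fold change 0.48 ± 0.10, adjusted p = 0.0167). FOS was at 1.93 ± 0.381 and 3.15 ± 0.232 TPM (adjusted p = 0.0506), FOSL2 at 2.61 ± 0.481 and 4.36 ± 1.59 TPM (adjusted p = 0.117) and JUND at 82.6 ± 12 and 64.5 ± 5.62 TPM (adjusted p = 0.0884). Of 21 tested members 1 rose, also when adjusted over the list alone, and 20 did not pass. The number that rose was 3 with median-of-ratios scaling and 4 with trimmed-mean scaling and with the correction for GC content. The list lay 0.27 above all tested genes (camera adjusted p = 0.000118, but adjusted p = 0.395 with an estimated correlation), but 0.061 above them among genes with a mean of at least 5 TPM, where it was not called (adjusted p = 0.0715), and 0.17 with a pseudocount of 5. DUSP1 lost its call without SEHBP-EGFP library 1 or 3 (adjusted p up to 0.0622).

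Genes of ribosomal proteins and the respiratory chain were higher as lists, with no member past the threshold. RPS25 was at 902 ± 102 and 1156 ± 118 TPM (adjusted p = 0.0851), RPL26 at 4872 ± 534 and 6261 ± 673 TPM (adjusted p = 0.138), RPL23 at 3760 ± 343 and 4573 ± 102 TPM (adjusted p = 0.163) and RPS27A at 1824 ± 197 and 2178 ± 94.2 TPM (adjusted p = 0.184). Of 53 ribosomal protein genes limma called 0, also when adjusted over the list alone, with 4 at an unadjusted p under 0.05 and 49 with log2 fold changes above 0. The list lay 0.20 above all tested genes (camera adjusted p = 1.3e-09, but adjusted p = 0.669 with an estimated correlation), and 0.12 above them without empty vector library 1 (adjusted p = 0.000159). Of 54 nuclear genes of the respiratory chain limma called 0, also when adjusted over the list alone, with 2 at an unadjusted p under 0.05. NDUFB3 was at 123 ± 18 and 149 ± 2.66 TPM (adjusted p = 0.122), NDUFS4 at 65.5 ± 9.92 and 78.4 ± 5.17 TPM (adjusted p = 0.174), UQCRB at 362 ± 50.8 and 424 ± 23.2 TPM (adjusted p = 0.211), and NDUFS5 had a log2 fold change of 0.22 ± 0.11 (adjusted p = 0.227). This list lay 0.15 above all tested genes (camera adjusted p = 3.6e-05, but adjusted p = 0.895 with an estimated correlation). Without empty vector library 1 it lay 0.086 above them and was not called (adjusted p = 0.0576). That library had the lowest TPM of all 6 in each of the 8 genes named here. With median-of-ratios scaling 3 ribosomal protein and 2 respiratory chain genes rose, with trimmed-mean scaling 3 and 4, and with the correction for GC content 2 and 0.

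Genes of cholesterol synthesis changed in both directions. MSMO1, a sterol methyl oxidase gene, went from 35.7 ± 2.33 to 48.6 ± 1.89 TPM (log2 fold change 0.44 ± 0.08, adjusted p = 0.0117), and the isomerase gene IDI1 from 53.9 ± 3.93 to 72.1 ± 4.69 TPM (0.41 ± 0.09). HSD17B7 went from 18.7 ± 2.04 to 12.2 ± 0.595 TPM (-0.57 ± 0.10) and the sterol reductase gene TM7SF2 from 22.5 ± 1.47 to 15 ± 0.951 TPM (-0.55 ± 0.09). Of 18 tested members 4 rose, 2 fell and 12 did not pass, and 4 rose and 3 fell when adjusted over the list alone. With the correction for GC content 4 rose and 1 fell, and TM7SF2 lost its call (-0.34, adjusted p = 0.0680). INSIG1, regulated by sterols and named after its value was seen, also rose (0.36). The list lay 0.11 above all tested genes (camera adjusted p = 0.0340, but adjusted p = 0.669 with an estimated correlation), and was not called without empty vector library 1 or SEHBP-EGFP library 1 or among genes with a mean of at least 5 TPM (adjusted p up to 0.0644). Without a filter on low TPM it lay 0.072 above all tested genes. MSMO1 lost its call without SEHBP-EGFP library 3 and IDI1 without library 1 or 3, and INSIG1 kept its call only without empty vector library 1 (adjusted p up to 0.0610, 0.0875 and 0.162).

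Targets of Wnt, TGF-beta and Notch signalling were slightly higher as a list. ID1 was at 12.3 ± 0.834 and 15.3 ± 1.02 TPM (adjusted p = 0.0828), HES1 at 32.1 ± 4.71 and 41.2 ± 4.62 TPM (adjusted p = 0.0977), ID3 at 101 ± 11 and 120 ± 9.13 TPM (adjusted p = 0.146) and ZNRF3 at 8.22 ± 1.11 and 9.67 ± 0.250 TPM (adjusted p = 0.249). Of 15 tested members limma called 0, also when adjusted over the list alone, with 3 at an unadjusted p under 0.05, and 3 rose with either scaling and 5 with the correction for GC content. The list lay 0.14 above all tested genes (camera adjusted p = 0.0185, but adjusted p = 0.669 with an estimated correlation). It was not called without empty vector library 1 (adjusted p = 0.0568) or without a filter on low TPM (adjusted p = 0.174), where it lay 0.079 above, and it lay 0.22 above among genes with a mean of at least 5 TPM. Across the 27 lists, camera called 10 with the preset correlation and 0 with an estimated one, and fry called 4: the p53, histone, splicing and ZNF lists (adjusted p = 0.0015, 0.0158, 0.0310 and 0.0310).

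**Figure D4:**
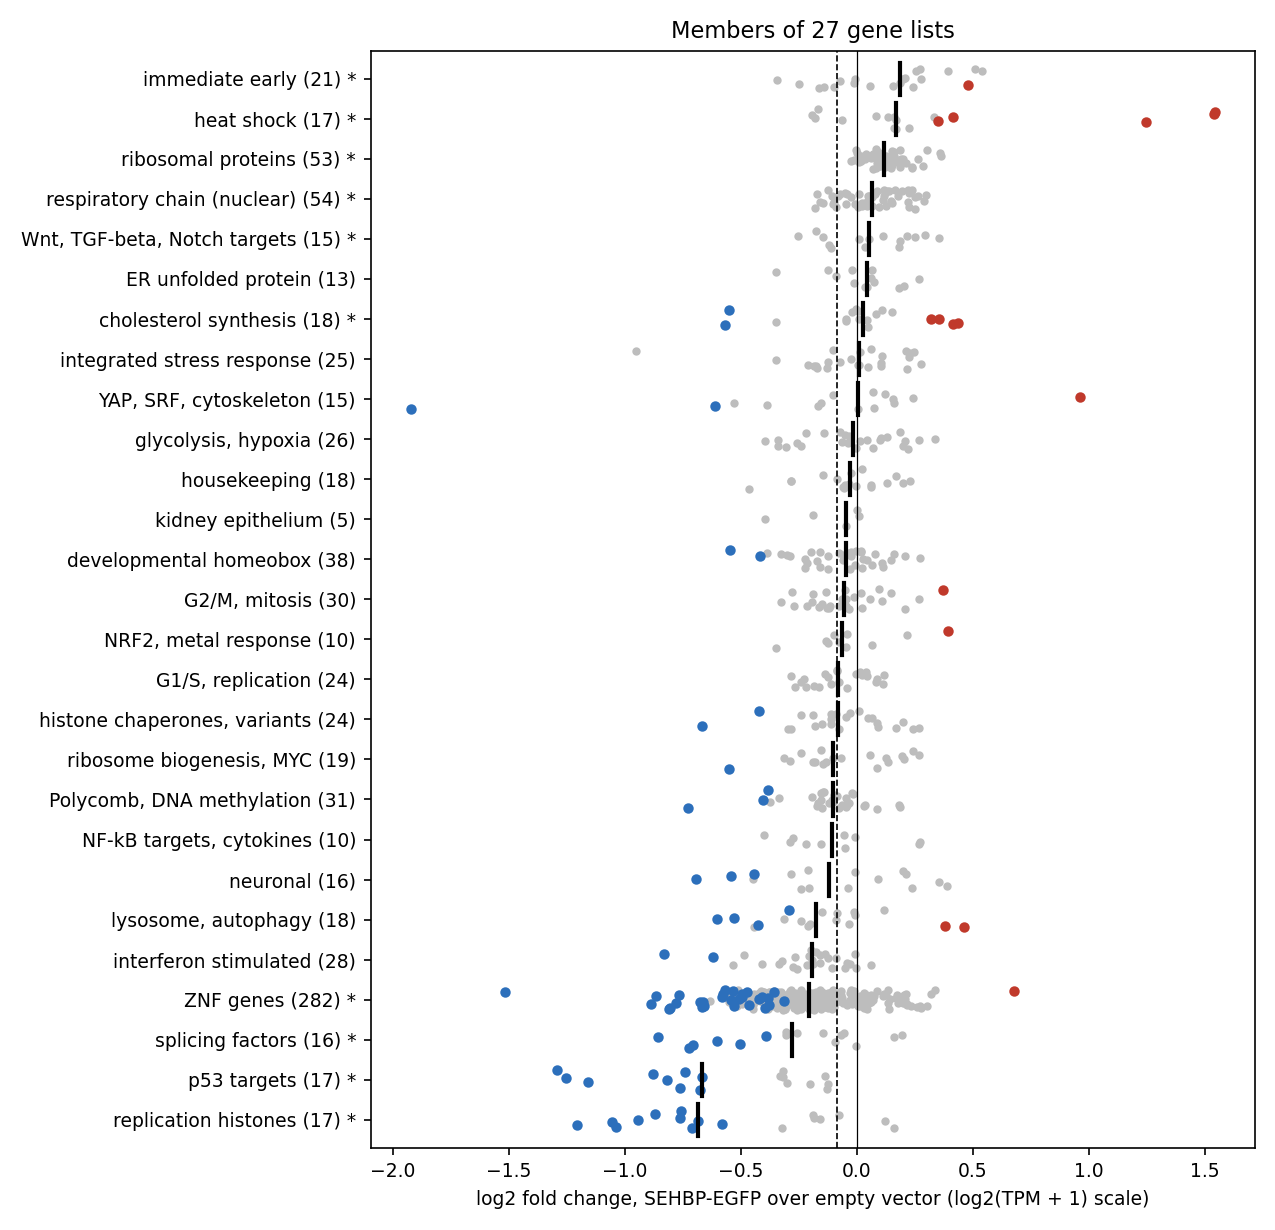
Log2 fold change of each tested member of 27 gene lists, with the number of tested members in brackets; red points rose, blue points fell, grey points did not pass, black bars are list medians and the dashed line is the median of all tested genes. An asterisk marks the 10 lists that camera called with a preset correlation.

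In 5 further lists single genes changed without a camera call. Of all 9332 tested genes 853 fell, and the interferon and homeobox lists had no larger share of falls. Among 28 interferon-stimulated genes 2 fell, also when adjusted over the list alone: the antiviral gene TRIM22 (7.19 ± 0.932 to 3.59 ± 0.342 TPM, adjusted p = 0.00557) and the RNA sensor gene DDX58 (6.98 ± 0.596 to 4.21 ± 0.744 TPM, adjusted p = 0.0176). Both scalings and the correction for GC content also gave 2 falls. Camera gave an adjusted p of 0.0606 for this list and called it in 7 of 16 alternatives. Of 15 YAP, SRF and cytoskeleton genes ANKRD1 rose, ACTA2 and the tropomyosin gene TPM2 (6.84 ± 0.411 to 4.13 ± 0.364 TPM) fell and 12 did not pass, with 1 risen and 2 fallen when adjusted over the list alone (camera adjusted p = 0.403). With either scaling 2 rose and 2 fell, and with the correction for GC content 2 rose and 1 fell. Of 38 homeobox genes HOXB13 (8.90 ± 1.02 to 5.75 ± 0.239 TPM) and HOXA7 (14.1 ± 1.20 to 10.3 ± 1.08 TPM) fell, and 1 fell when adjusted over the list alone (camera adjusted p = 0.606). Either scaling and the correction for GC content gave 1 fall, and trimmed-mean scaling and the correction also 1 rise. Of 16 neuronal genes SYP, of synaptic vesicles (9.56 ± 1.32 to 5.51 ± 0.446 TPM), RBFOX3 (-0.54 on the log2 scale) and INA (-0.44) fell, and 1 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.927). Of 18 lysosome and autophagy genes 4 fell and 2 rose, and 6 fell and 2 rose when adjusted over the list alone (camera adjusted p = 0.493). Among these were FLCN (-0.53 on the log2 scale), NEU1 (-0.43) and WIPI1 (0.46), and ATP6V0D1 (-0.29) and GABARAPL1 (0.38), the last 2 named after their values were seen. TRIM22, ACTA2, TPM2, ANKRD1 and SYP kept their calls whichever library was left out, but TPM2 and SYP lost theirs with the correction for GC content and without a filter on low TPM (adjusted p up to 0.0676 and 0.0590), and ACTA2 without a filter.

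The other genes named in these 5 lists each lost their call in more than 1 of the fits with 1 library left out. These fits have less power, and the log2 fold change of INA, for example, stayed between -0.47 and -0.43 in them. DDX58 lost its call without SEHBP-EGFP library 1 or 3 (adjusted p up to 0.0668) and HOXB13 without empty vector library 2 or 3 or SEHBP-EGFP library 3 (up to 0.0626). HOXA7, RBFOX3 and ATP6V0D1 kept theirs only without empty vector library 1 (up to 0.138, 0.134 and 0.132), and INA only without empty vector library 1 or SEHBP-EGFP library 2 (up to 0.0796). FLCN kept its call only without empty vector library 2 or SEHBP-EGFP library 3, WIPI1 only without empty vector library 1 or SEHBP-EGFP library 1, NEU1 only without SEHBP-EGFP library 1, and GABARAPL1 only without empty vector library 1 or 2 (up to 0.103, 0.158, 0.178 and 0.0848). With the correction for GC content, 2 lysosome and 2 neuronal genes rose and 0 of either fell. With either scaling 2 lysosome genes rose and 1 fell, and 2 neuronal genes rose and 2 fell.

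In the remaining 10 tested lists at most 1 gene was called. Limma called 0 of 10 NF-kB targets and cytokines (2 at an unadjusted p under 0.05), 0 of 13 genes of the unfolded protein response (3), 0 of 25 of the integrated stress response (2), 0 of 24 of G1/S and replication (4), 0 of 26 of glycolysis and hypoxia (6), 0 of 5 of kidney epithelium (1) and 0 of 18 housekeeping genes (3), and 0 in each when adjusted over the list alone. With either scaling 3 genes of the unfolded protein response, 2 of glycolysis and hypoxia, 2 housekeeping genes, 2 mitotic genes, 1 NF-kB target and 1 gene of the integrated stress response rose. With the correction for GC content these numbers were 2, 1, 1, 2, 0 and 1, and 1 gene of G1/S and replication rose. ANLN rose among 30 mitotic genes (0.37) and TXNRD1 among 10 NRF2 and metal response genes (0.39), and RRP9 fell among 19 genes of ribosome biogenesis (-0.55), all 3 named after their values were seen. Adjusted over the list alone, 0 mitotic genes and 1 NRF2 gene rose and 2 genes of ribosome biogenesis fell. RRP9 kept its call whichever library was left out but not with the correction for GC content (adjusted p = 0.0515), ANLN kept it only without empty vector library 1, and TXNRD1 only without empty vector library 1 or SEHBP-EGFP library 1 (adjusted p up to 0.184 and 0.0897). Camera's adjusted p was between 0.0606 and 0.927 for lists it did not call, of which it called the unfolded protein and integrated stress response lists in 5 and 3 of 16 alternatives. Camera compares a list with the other genes, and its direction was up while the median or mean of the deposited values was below 0 for the chaperone, NF-kB, integrated stress response, YAP, G1/S, mitotic, glycolysis, ribosome biogenesis, homeobox, neuronal, NRF2 and housekeeping lists.

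Markers of other cell types were too few to test as lists. Of the germline genes 3 had a mean of at least 1 TPM, with PRAME highest at 49.5 TPM, and of the fibroblast markers 3, with VIM highest at 533 TPM. Of the leukocyte markers 2 reached that level, with CORO1A highest at 7.91 TPM. Of the erythroid markers 2 did, and both changed: HBA1 rose from 2.75 ± 0.642 to 5.21 ± 1.14 TPM, and EPOR, named after its value was seen, fell by 0.44 on the log2 scale. EPOR kept its call only without SEHBP-EGFP library 2 (adjusted p up to 0.123). Mitochondrially encoded genes were not analysed here.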

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

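The fit with GH1 left out and the correction for GC content were chosen after the results were seen. Genes changed at least 2-fold, 59 as reported, numbered 128 and 8 with pseudocounts of 0.1 and 5, 29 without a filter on low TPM, 29 with a mean of at least 5 TPM, 38 and 37 with median-of-ratios and trimmed-mean scaling, and 29 with the GC correction. The pseudocount sets the fold change of low genes, and the stricter filter tests fewer of them; for the scalings and the GC correction the cause was not tested. Without a filter 272 genes passed among 16558 tested. Leaving out each library in turn gave 379 to 1216 called genes, 48 to 66 changed at least 2-fold, 6 to 12 called lists and a ZNF family median of -0.16 to -0.078 relative to all tested genes. The fewest lists, 6, came without empty vector library 1. With an estimated correlation 0 lists were called, and the ZNF family, at -0.12, had an adjusted p of 0.669. All 940 called genes kept their sign in every setting in which they were tested. Over 102 genes chosen by the rule or after their values were seen, and 1604 comparisons with an alternative, 997 kept a call, 214 stayed uncalled, 353 lost a call, 40 gained one and 0 changed sign. Of the 86 that were called, 59 lost their call without a filter, 25 with the GC correction, 21 with the replicate block, 16 and 17 with median-of-ratios and trimmed-mean scaling, 14 without a mean-variance trend, 8 and 4 with pseudocounts of 0.1 and 5, and 5 with GH1 left out. Of these 86, 35 kept their call in every fit with 1 library left out in which they were tested, and 51 lost it without at least 1. The p53, histone, heat shock and ribosomal protein lists were called in all 16 alternatives with the preset correlation.

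The replicate numbers do not pair the libraries: deviations from the group means of libraries with the same number correlated at -0.022, 0.037 and -0.044 across genes. With the replicate number as a block, 736 genes passed, 56 of them changed at least 2-fold, and 11 lists were called. The depth of the libraries is unknown, so what it limits cannot be stated.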

Other observations

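Tests chosen after the result was seen were those of a common scale difference, of short-lived mRNAs, of EGFP alone, of pseudogenes, cilia genes and retained introns, and of other splits of the libraries, and the fits with GH1 left out and with the correction for GC content. Unprocessed pseudogenes, copies of genes that keep their intron structure, lay lower than random lists of coding genes of the same expression, which ignore correlation between genes. Of 206 tested, 51 fell, 153 did not pass and 2 rose, CCDC144B and FAAHP1, the latter with a call kept only without empty vector library 2 (adjusted p up to 0.125). Their median log2 fold change was -0.31, below 10000 random lists matched on mean expression, whose middle 95% of medians ran from -0.18 to -0.095. With the GC correction the median was -0.20, also below all random lists. As the idea came from falls already seen, the test was repeated without 44 members seen to change and without such genes in the random lists: the median of the other 162 was -0.21, below all random lists (-0.17 to -0.081). For these 162 genes camera gave an unadjusted p = 0.0369 with the preset correlation and p = 0.106 with an estimated correlation, so the hypothesis was not settled. Processed pseudogenes, copies made from mature mRNA, lay higher: of 320 tested, 9 rose and 9 fell, with a median of 0.016, above all random lists (-0.16 to -0.098), and of 0.12 with the GC correction (-0.045 to 0.013). Camera gave them an unadjusted p = 1.8e-05, and p = 0.0371 with an estimated correlation. Reads of pseudogenes can be divided wrongly with their parent genes, so single members are uncertain.

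Genes of cilia and axonemes, taken by symbol prefix after falls of BBS1, DRC3 and CFAP69 were seen, lay lower than random lists, a hypothesis that was not settled either. Of 34 tested, 7 fell: BBS1 (log2 fold change -1.24, 16.3 ± 3.45 to 6.62 ± 3.04 TPM), DRC3 (-0.96), CFAP69 (-0.87), IFT172 (-0.53), CFAP77 (-0.50), IFT46 (-0.41) and IFT81 (-0.39). DNAH14 rose (0.43). The median was -0.26, at the 0.04 percentile of 10000 random lists matched on mean expression, and -0.18 with the GC correction. Without the 4 members seen before, these and DNAH14, the other 30 had a median of -0.24, against -0.19 to -0.012 for the middle 95% of random lists. For these 30 genes camera gave an unadjusted p = 0.0138 with the preset correlation and p = 0.197 with an estimated correlation. CFAP69 alone of these 8 genes kept its call whichever library was left out. BBS1 and DRC3 lost theirs without SEHBP-EGFP library 1 (adjusted p = 0.0573 and 0.0540), CFAP77 whichever library was left out, and the other 4 without 2 or more libraries (adjusted p up to 0.113). Without a filter on low TPM IFT46 alone kept its call, and DRC3, IFT172 and CFAP77 lost theirs with the GC correction. A hypothesis on retained introns was not borne out: the 2236 coding genes with the highest share of annotated retained-intron transcripts had a median only -0.031 from that of the 3697 genes with none, although 12.5% against 7.03% of them were called lower.

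Many more genes fell than rose. With GH1 left out and the other genes rescaled to a common total, 91.2% of called genes still fell. The rescaling also scaled up empty vector library 1, whose listed total was lowest, and the median of all tested genes went from -0.087 to -0.11. So this fit cannot tell how much TPM taken up by GH1 added to the excess. With the GC correction the share of called genes that fell was 54.4%. Log2 fold changes correlated with GC content across genes (Spearman's rho = -0.257), so a trend with GC content may account for the excess, although the correction also centres each library. With median-of-ratios scaling the share was 61.6%, and without spike-ins or counts a common scale difference cannot be told apart from a fall of most genes. A fall of most genes caused by SEHBP stays open as well.

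Of 17 p53 targets 9 fell. A scale difference or GC trend alone is argued against by the median of the list with the GC correction, -0.49, with a 75th percentile of -0.16. A general fall of short-lived mRNAs was tested through the immediate early list. Its median was 0.19, with a 25th percentile of -0.073 against a 75th of -0.30 for the p53 list, so these short-lived mRNAs did not fall as a list. Immediate early genes are induced by stress, and heat shock genes rose. Higher transcription could therefore hide a loss of short-lived mRNAs, and the test cannot exclude one. The share of transfected cells or plasmid load, tracked by GH1, stays open: in the empty vector library with the most GH1 the mean of the p53 targets lay only -0.028 from that of the other two on the log2 scale. In the SEHBP-EGFP library with the most GH1 it lay 0.0028 above the mean of the other two, and the lowest mean was in library 1. Both go against this explanation, but 1 library per group excludes nothing. With 0 libraries from cells given EGFP alone, an effect of EGFP or of the amount of foreign protein cannot be told apart from one of SEHBP. A lower activity of this pathway with SEHBP-EGFP is a hypothesis that these data could not settle.

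GH1 was abundant in both groups. Many pCMV6 plasmids carry a growth hormone polyadenylation region, and reads of such a region may have been assigned to GH1: its lowest value over the 6 libraries was 6297 TPM, while the highest mean among other pituitary genes was 1.27 TPM (CGA). Cells of another type that express growth hormone were tested through PRL, listed at 0 TPM in every library. PRL is the gene of another hormone, prolactin, so its absence cannot show whether cells that make growth hormone were present. GHRHR and POU1F1 were not analysed here, and a value listed at 0 can be a failed estimate, so this explanation cannot be told apart from the first by that test alone.

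Among the 10 splits of the 6 libraries into 3 and 3, the real one gave 940 called genes against a highest other value of 1, and 59 genes changed at least 2-fold against 1, so 1 of 10 splits was as large in each case. For called lists, 2 of 10 splits gave as many, with 10 in the real split and 11 in another. With 10 splits the share cannot be below 0.1. Each other split puts libraries of both groups together. Part of the real difference therefore stays between its groups, and part adds to the spread within them. So the other splits do not show what would arise with no difference, for genes or for lists. Another split gave the histone list a lower p than the real one (adjusted p = 4.4e-06 against 0.000112), with 4 other splits past the threshold. For the ZNF family 4 of 10 splits gave as low a p, with 5 others past the threshold. The p53 and heat shock lists had their lowest p in the real split but were called in 3 others each. The median of the p53 list lay 0.58 from that of all tested genes in the real split and at most 0.19 in the others, while 5 of 10 splits gave the ribosomal protein list as low a p and 6 of 10 the respiratory chain list.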
